A study of Rattus norvegicus with 18 samples.

How the data were processed

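Testes of Wistar rats aged 8 weeks were measured in a chronic sleep restriction (CSR) group and a control group. The labels give 3 CSR and 3 control RNA-seq libraries, although the series text speaks of 6 samples per group, and 6 CSR and 6 control libraries of reduced representation bisulfite sequencing (RRBS), in which DNA cut with MspI is treated with bisulfite so that methylated cytosines can be read at CpG sites. Groups and replicate numbers were taken from the labels, which do not say that the RNA and methylation libraries share animals. The labels also do not say that each library came from its own animal, so p-values measure the spread between these samples, which may be technical. The codes that the submitters gave control RNA libraries 1 and 2 differ only in their last digit, and both were kept as separate libraries. In the codes of the methylation libraries, those labelled control carry the letter that marks CSR in the RNA codes; the labels were kept, and the direction of every methylation difference rests on them.

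The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for RefSeq transcripts. Per the submitters' processing notes, Trimmomatic, HISAT2, StringTie and the rn6 build were used; versions, settings and the rule that selected the transcripts are not given in the sources used here. Poly(A) RNA was used, per the labels' protocols. The low FPKM values showed no steps of whole reads, so the depth of the RNA libraries is unknown. Of the accessions, 6911 matched a symbol in the RefSeq gene table of assembly GRCr8, giving 6682 distinct symbols, and 105 did not match. The deposited methylation tables give, per the file headers, the read count (coverage) at each cytosine of a CpG and the percent of its reads read as C or T. The processing notes name Trim Galore, Bismark, SAMtools and rn6. The lowest coverage in the deposited tables was 5 reads, and coverage times percent gave whole reads within the rounding of the percent. Reads of both strands of a CpG were summed.

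RNA was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1). The 5657 transcripts with at least 1 FPKM in at least 3 libraries were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low transcripts. Gene lists of testis cell types, stress, endocrine, clock and housekeeping functions were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Each list with at least 4 tested members was compared with all other tested transcripts by camera with a preset correlation of 0.01, two-sided; camera with an estimated correlation was run beside it, and fry, which tests a list against no change and not against other transcripts. Named transcripts are the 10 largest rises and 10 largest falls in log2 fold change among named genes past the threshold whose groups did not overlap, and up to 3 members per list past 0.05 adjusted over the list alone; up to 3 members per list with the highest means may be given as values.

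For methylation, CpGs with at least 10 reads in all 12 libraries and no library above its 99.9th percentile of coverage were kept. Library means over these CpGs were compared by a two-sided exact permutation test over all 924 assignments, whose smallest possible p is 0.00216. Each CpG, and each 1000-bp tile with at least 3 such CpGs, was tested with a quasi-binomial logistic model of methylated and unmethylated reads, with the dispersion moderated across sites by limma's squeezeVar. A call required an adjusted p under 0.05 and a difference of at least 10 percentage points for a CpG or 5 for a tile. Where fewer than 6 tiles passed in a direction, the 3 with the smallest p are given as not passing. RRBS reads carry no molecular identifiers, so the model's sampling term covers counting error only.

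No annotation of the rn6 build was used here. Promoters, annotation classes, promoter methylation of the gene lists and its relation to expression were therefore not analysed here, and coordinates are given without gene context. Classes of CpGs by mean level, by CpG density per 1000 bp and by chromosome replaced the annotation classes; they were chosen after seeing the data. CpGs were called genotype-like where all 12 libraries lay within 15 points of 0, 50 or 100% and no level was held by more than 9 libraries, a definition also chosen after seeing the data.

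The tests were checked on simulated data. In the RNA comparison of 5657 transcripts, 25% of 100 transcripts changed by 1 and 67% of 100 changed by 2 on the log2 scale were called, with 2 calls among 5457 unchanged ones. Of 100 CpGs changed by 20 points, 0% were called, and of 100 changed by 40 points, 33%, among 643957 CpGs, with 1 call among 643757 unchanged ones. Of 100 tiles changed by 10 points, 2% were called, and of 100 changed by 20 points, 18%, among 93313 tiles, with 0 calls among 93113 unchanged ones. The changed CpGs and tiles were drawn only from those with a level of 30 to 70% over all reads. Of the 643957 CpGs, 47537 had a mean level in that range and 314711 one of 90% or more. Changes at other levels were not simulated, so these shares do not hold for CpGs or tiles in general. The simulated methylation libraries were independent of one another, unlike CSR libraries 2 and 3, which were alike as described below. The count of calls among unchanged CpGs therefore need not hold here, where other splits of the real libraries called up to 26 CpGs. Alternatives covered the pseudocount, filters on low values, normalization, variance models, coverage limits, site selection, tile length, the replicate number as a block and leaving out each library. Versions of data.table and matplotlib were 1.17.8 and 3.10.9.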

Results

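RNA-seq and RRBS libraries from rat testis were compared between chronic sleep restriction and control, to ask which transcripts and which CpG methylation levels differed after sleep restriction. The RNA table holds 3 CSR and 3 control libraries, with median values of 3.69 to 3.97 FPKM per library and unknown read depth. The 12 methylation libraries hold between 46257452 and 68940379 reads at CpG cytosines. At the 643957 CpGs kept, the median coverage per library lay between 29 and 42 reads.

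In the RNA comparison 25 of 5657 transcripts were called by limma, 13 higher and 12 lower in CSR, and 748 had an unadjusted p under 0.05. The largest rises were in *Tom1*, *Eqtn* and *Ldhal6b*, while *Rpl15* and *Tra2a* fell and were listed at 0 in all CSR libraries. *Eqtn* (NM_001039345), which encodes an acrosomal membrane protein, stood at 24.8 ± 9.14 FPKM in CSR and 1.90 ± 0.426 in control (SD, n = 3 each), a log2 fold change of 3.09 with a standard error of 0.31 and an adjusted p of 0.0269. *Ldhal6b* (NM_183334), a lactate dehydrogenase paralog, had 65.7 ± 19.2 FPKM in CSR and 7.66 ± 3.15 in control. *Ccna1* (NM_001011949), a cyclin required for male meiosis, had 7.46 ± 2.84 against 0.817 ± 0.0732 FPKM. *H2bc1* (NM_022643), a testis histone, had 13.4 ± 2.74 against 2.30 ± 1.03 FPKM. *Plaat5* (NM_001039007), of a family of phospholipases and acyltransferases, read 105, 134 and 175 FPKM in the CSR libraries and 29.8, 32.7 and 37.0 in the control libraries.

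Further called rises were *Tom1* (NM_001008365), an adaptor of endosomal traffic, at 31.0 ± 1.76 FPKM in CSR and 1.09 ± 1.28 in control, and *Rpph1* (NR_002703), the RNA component of RNase P, at 15.1 ± 1.71 and 1.85 ± 0.245 FPKM. The log2 fold change of *Tom1* was 4.10 (standard error 0.40, adjusted p 0.0269) and that of *Rpph1* was 2.50 (standard error 0.15, adjusted p 0.00449). Poly(A) RNA was used, and whether that selection bears on the values of *Rpph1* was not tested. *Ddx52* (NM_053525), an RNA helicase, had 6.26 ± 1.36 FPKM in CSR and 0.805 ± 0.0433 in control, and *Map2k7* (NM_001025425), a kinase of the JNK pathway, had 4.14 ± 1.22 and 0.205 ± 0.0228 FPKM. *Zfp362* (NM_001191612), a zinc finger gene, read 3.37, 3.72 and 3.33 FPKM in CSR and 0.271, 0.263 and 0 in control.

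Falls with values above 0 in all libraries were led by a splicing factor and an amino acid transporter subunit. *Srsf2* (NM_001009720), a splicing factor, had 1.15 ± 0.433 FPKM in CSR and 16.6 ± 3.00 in control, a log2 fold change of -3.03 (standard error 0.21, adjusted p 0.00756). *Slc3a2* (NM_001271089), the heavy chain of amino acid transporters, had 2.22 ± 0.357 and 16.4 ± 1.86 FPKM, a log2 fold change of -2.43 (standard error 0.15, adjusted p 0.00482). The deposited data hold another transcript of *Slc3a2*, not reported here, so this fall is of a transcript and not of the whole gene. *Acp6* (NM_001031645), a lysophosphatidic acid phosphatase, had 0.285 ± 0.0858 and 4.82 ± 1.66 FPKM. The called transcripts outside the naming rule, listed after their values were seen, were *Ess2*, *Foxk1* and *Srsf4*, which rose, and *R3hdm2*, which fell, besides *Mcm3*, which was listed at 0 in all CSR libraries and read 2.21, 2.47 and 2.21 FPKM in control.

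Of the 12 called falls, 8 were listed at 0 in all 3 CSR libraries. They include *Rpl15* (NM_139114), a ribosomal protein gene used by every cell, with 29.1, 29.3 and 46.7 FPKM in control libraries 1 to 3, and the splicing factor *Tra2a* (NM_001126296), with 8.01, 8.72 and 9.15 FPKM. *Rcc1l* (NM_001108332) had 3.71, 4.51 and 5.48 FPKM in control, and *Ivd* (NM_012592), an enzyme of leucine breakdown, had 5.33, 3.01 and 2.66. *Zdhhc9* (NM_001039016), a palmitoyltransferase, had 3.43, 3.34 and 2.76 FPKM in control, and *Trabd* (NM_001106788) had 2.64, 2.69 and 3.30. *Col1a1* (NM_053304), a collagen of peritubular and other stromal cells, had 2.30, 2.14 and 2.73 FPKM in control. An exact 0 can be a failed estimate, so no fold is given for these transcripts. In the whole data set, 202 transcripts were listed at 0 in all CSR libraries and above 0 in all control libraries, and 1 transcript the other way round. Of the 202, 199 had a control mean under 4 FPKM. The rule that selected the transcripts is not given, so its part in this difference is not known. The libraries held 1183, 1000 and 1415 values at 0 in CSR and 330, 275 and 423 in control.

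**Figure D1:**
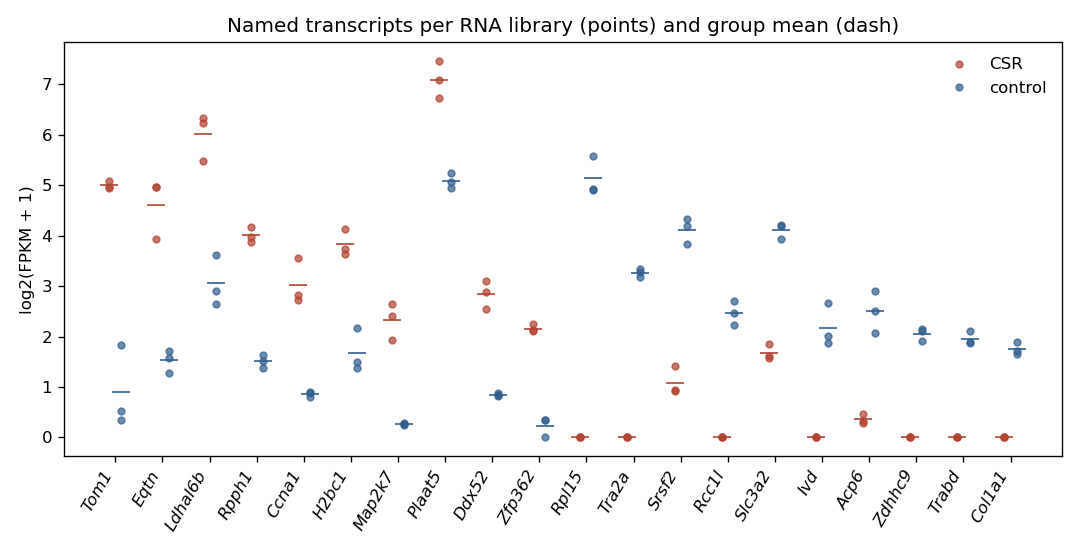
Values of the named transcripts in each RNA library on the log2(FPKM + 1) axis, with points for libraries and dashes for group means (3 CSR and 3 control libraries). Non-overlapping groups are part of the naming rule, and *Rpl15* lies at 0 in all CSR libraries.

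**Figure D2:**
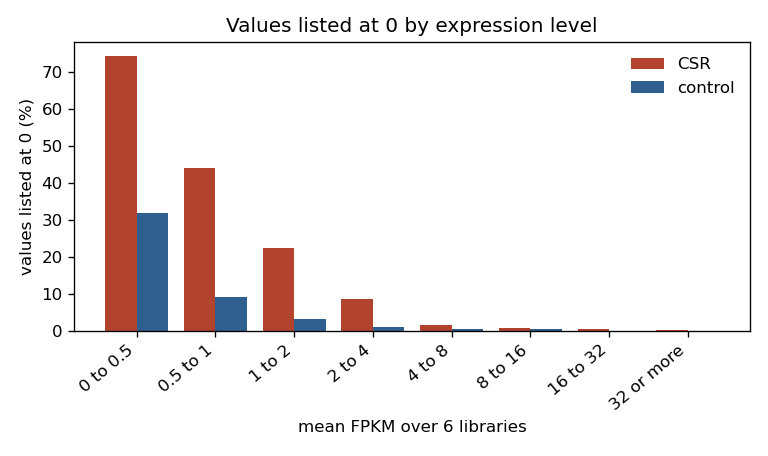
Percent of values listed at 0 (vertical axis) in classes of mean FPKM over the 6 libraries (horizontal axis), which values of 0 also lower, for CSR and control. In the class under 0.5 FPKM, 74.3% of CSR and 31.8% of control values were at 0; at 32 FPKM or more, 0.116% and 0.0774% were.

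The count depended on single libraries. It was 259 without control library 3, 4 without control library 2, 8 without control library 1, 7 without CSR library 3 and 14 without CSR library 2; with control libraries 1 and 2 counted as 1 library it was 7. Single transcripts differed in this: *Rpph1* passed in 15 of 16 alternatives, *Rpl15* in 14 of 15, *Slc3a2* in 14 of 16 and *Tra2a* in 13 of 14, but *H2bc1* in 6 of 16, *Acp6* in 6 of 15, *Zfp362* and *Zdhhc9* in 6 of 14, and *Ivd*, *Trabd* and *Col1a1* in 5 of 14. The other named transcripts among the largest rises and falls passed in 8 to 12. An alternative whose filter removes a transcript is left out of the count of that transcript. Those with a value at 0, *Rpl15* and *Tra2a* included, were therefore not judged among transcripts above 0 in all libraries. The CSR values of *Rpl15* and *Tra2a* also have no spread. At 206 of the 259 transcripts called without control library 3, that library lay nearer the CSR mean than the mean of the other control libraries. These transcripts were chosen without it, for a difference of the other controls from CSR. That choice by itself can move its place towards CSR.

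Among the gene lists, ribosomal proteins were called higher in CSR by camera with an adjusted p of 0.04997, close to the threshold: 48 of 71 tested members had a positive and 23 a negative log2 fold change, with a median of 0.14. The call was lost with an estimated correlation (adjusted p = 0.982) and with quantile normalization (adjusted p = 0.99). Tested by fry against no change, which is another question, the list had an adjusted p of 0.767. Over the alternatives run for the lists, the adjusted p ranged from 0.00318 to 0.99. No member rose past the threshold over all transcripts or adjusted over the list alone, and *Rpl15* fell by both. Elongating spermatid genes had an adjusted p of 0.0566 by camera and did not pass, with 17 members positive and 7 negative; the median log2 fold change was 0.17 and the mean 0.63. Most of that mean came from *Prm1* and *Prm2*, protamine genes looked at after their values were seen, whose log2 fold changes of 7.59 and 4.78 did not pass and rest on values under 1 FPKM in control libraries 1 and 2. Among its members, *Tnp1*, a transition protein that replaces histones, read 3903, 7202 and 7415 FPKM in CSR and 4298, 4411 and 7730 in control. *Oaz3* read 4528, 4287 and 4210 FPKM in CSR and 2148, 2894 and 4374 in control.

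Other germ cell lists did not pass. Of 24 round spermatid genes, 2 rose past the threshold over all transcripts and the same number adjusted over the list alone, *Eqtn* and *Plaat5*; 12 members were positive and 12 negative, with a camera adjusted p of 0.852, a median of -0.04 and a mean of 0.34. Of 15 meiotic spermatocyte genes, 1 rose, *Ccna1*, also adjusted over the list alone, and the list had a camera adjusted p of 0.82. Of 6 spermatogonial genes none passed.

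Lists of somatic cells, through which other cell types in the testis can be followed, did not pass either. Leydig cell genes (7 tested, camera adjusted p 0.852) had a median log2 fold change of -0.03; *Insl3*, a Leydig cell hormone, had 57.5 ± 10.4 FPKM in CSR and 42.6 ± 12.1 in control. Of 12 Sertoli cell genes, *Ctsl*, a lysosomal protease, fell only adjusted over the list alone, with 31.2 ± 1.55 FPKM in CSR and 40.4 ± 0.673 in control. Among 9 peritubular myoid genes *Col1a1* fell past both thresholds, and of 8 macrophage and immune genes none passed. Lists of endothelial, blood, epididymal and mitochondrially encoded genes had too few tested members.

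In the stress and endocrine lists, *Dusp1*, a phosphatase induced by glucocorticoids and an immediate early gene, was listed at 0 in all CSR libraries and read 1.13, 1.72 and 1.52 FPKM in control; it passed only adjusted over those lists alone (adjusted p 0.143 over all transcripts). *Prdx2*, a peroxiredoxin of the oxidative stress list, had 25.4 ± 3.70 FPKM in CSR and 14.2 ± 2.03 in control and likewise passed only adjusted over the list alone. No member of the clock, steroidogenesis, cholesterol synthesis, retinoic acid, gonadotropin and androgen signalling, inflammation, apoptosis, glycolysis, flagellum, blood-testis barrier, DNA methylation, ubiquitin and autophagy, or endoplasmic reticulum and heat stress lists passed by either adjustment. Camera adjusted p-values of all lists except ribosomal proteins and elongating spermatids lay between 0.605 and 0.98. The sign of the median differed from that of the mean or of the camera test for Leydig cell, round spermatid, immediate early, glucocorticoid response, blood-testis barrier, DNA methylation and gonadotropin and androgen signalling genes. *Cyp17a1*, an enzyme of androgen synthesis, had 18.5 ± 8.93 FPKM in CSR and 19.6 ± 10.7 in control, and the clock gene *Per1* had 15.3 ± 0.658 and 14.6 ± 2.29.

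Mean CpG methylation was 65.5 ± 0.422% in libraries labelled CSR and 65.5 ± 0.504% in libraries labelled control (SD, n = 6 each), a difference of 0.056 percentage points with a 95% interval of -0.541 to 0.654 (exact permutation p = 0.827). The difference was 1.64 points with CpGs weighted by reads (exact permutation p = 0.335) and -0.241 points without control libraries 3 and 5, whose coverage profiles differed from the others. None of 11 classes by level, density or chromosome passed after adjustment. The smallest p was in CpGs with a level of 90% or more, at 95.7 ± 0.064% in CSR and 95.4 ± 0.262% in control (n = 6 each, exact permutation p = 0.013, adjusted p = 0.143); without control library 1, 1 class passed. Control libraries 3 and 5 were the lowest in it, and without them the smallest adjusted p of any class was 0.471. CpGs with a level under 10% had 2.03 ± 0.714% in CSR and 2.03 ± 0.529% in control.

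**Figure D3:**
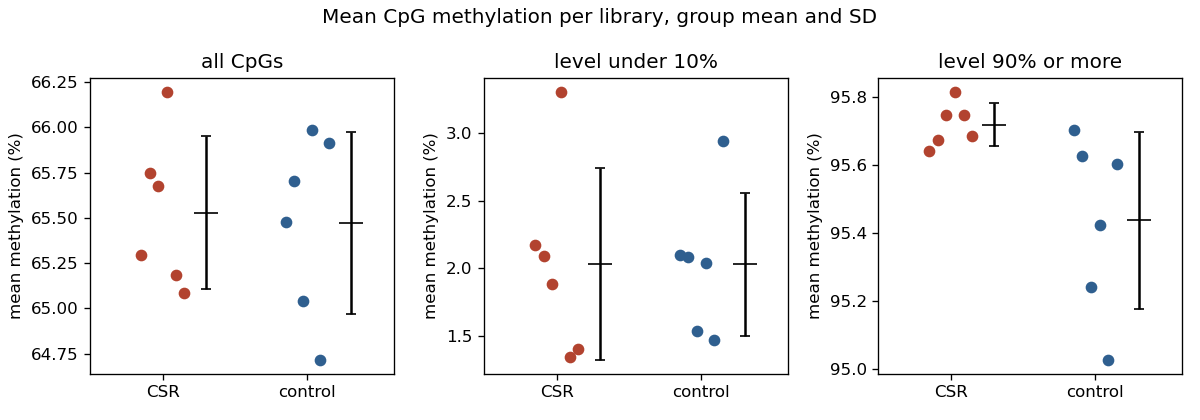
Mean methylation in percent per library for all 643957 CpGs, those with a level under 10% and those of 90% or more; points are libraries, dashes and bars are group means and SD (6 CSR and 6 control libraries). The vertical axes do not start at 0, and the group ranges overlap in each class.

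A single CpG was called among 625171 tested by the quasi-binomial model, and 45852 had an unadjusted p under 0.05. It lies on chromosome 6 from 2754555 to 2754556 (rn6; gene context not analysed here). Its methylation was 96.7 ± 1.88% in libraries labelled CSR and 42.1 ± 30.9% in libraries labelled control, a difference of 54.7 points (n = 6 each, adjusted p = 0.0216 by the moderated model), at 34 to 142 reads per library. The control libraries read 40.8, 43, 94.1, 0, 26.5 and 47.9%. The 4 other CpGs kept within 200 bp differed by a median of 1.23 points between groups. The call was lost with a coverage minimum of 5 reads, without moderation and with limma on log ratios (0 calls each).

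**Figure D4:**
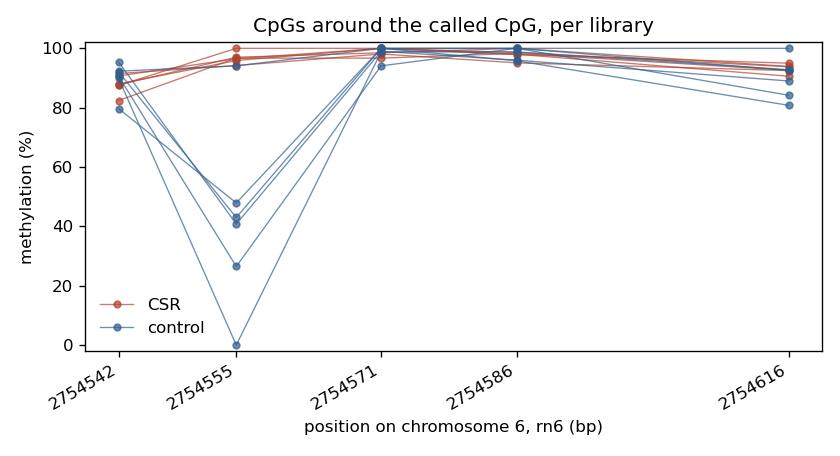
Methylation in percent (vertical axis) of 5 CpGs by position on chromosome 6 (horizontal axis, bp), 1 line per library. Control libraries spread from 0 to 94.1% at 2754555, and all libraries stand at 79.7% or more at its neighbours.

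No tile was called among 93256 tested by the quasi-binomial model, none with limma on log ratios, and 5750 had an unadjusted p under 0.05; the smallest adjusted p was 0.377. Among the tiles with the smallest p, none of which passed, 1 on chromosome 20 from 20753001 to 20754000 held 98.5 ± 1.64% in CSR and 81.2 ± 8.79% in control, at 103 to 292 reads per library. It contains a genotype-like CpG, from 20753798 to 20753799, with 99.6 ± 1.09% in CSR and 46.7 ± 31.7% in control; without that CpG the tile held 98.0 ± 2.45% and 96.6 ± 2.56%, a difference of 1.40 points. Another on chromosome 10 from 48317001 to 48318000 held 93.4 ± 4.17% and 79.5 ± 4.34%, at 95 to 624 reads. The tile on chromosome 6 from 2754001 to 2755000, which contains the called CpG, held 94.2 ± 1.10% and 84.2 ± 6.92%, at 173 to 771 reads. Lower values in CSR were seen on chromosome 17 from 28077001 to 28078000, with 0% methylated reads in each CSR library, at 121 to 230 reads, and 7.70 ± 4.57% in control, at 118 to 254 reads; control library 1 was also at 0%. On chromosome 16 from 36094001 to 36095000 the values were 8.24 ± 3.60% and 22.0 ± 3.09%, at 204 to 562 reads, and on chromosome 12 from 45908001 to 45909000 they were 76.3 ± 5.03% and 89.4 ± 2.93%, at 162 to 433 reads. Without control library 2, 3 tiles and 16 CpGs were called.

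CSR libraries 2 and 3 held the same level at 97.8% of 957 genotype-like CpGs, whereas the other 65 pairs of libraries shared between 37.5 and 51.2%. The methylated read counts of CSR libraries 2 and 3 differed by 2.72 times binomial sampling noise, and other pairs by 2.91 to 4 times, which does not show whether the pair shares an animal. The labels do not say so, and both were kept as separate libraries; summed as 1 library, they left 0 called CpGs and 0 called tiles.

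**Figure D5:**
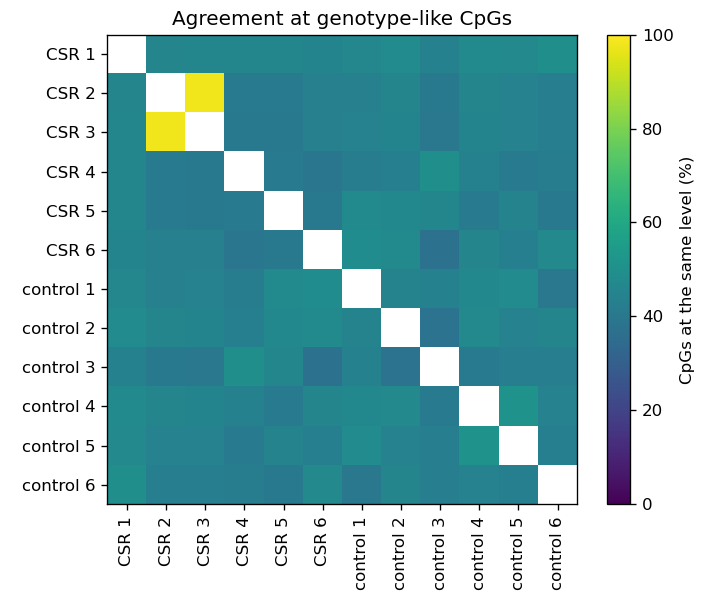
Percent of the 957 genotype-like CpGs at the same level in each pair of the 12 methylation libraries (both axes list the libraries). The pair of CSR libraries 2 and 3 stands at 97.8%, all others at 51.2% or less.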

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

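Among 46 groups of 6 libraries examined for a library far from the others, 3 gave one, against 2.3 by chance. CSR library 6 had 68940379 reads at CpGs, against 46257452 to 54712419 in the other CSR libraries. Control library 2 had 49647718 reads, against 59342162 to 64654061 in the other control libraries. The mean coverage correlation of CSR library 5 with all other libraries was 0.553, against 0.624 to 0.638 in the rest of its group.

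Of the tests in this part, those for another row of the same gene, for other splits of the zeros and for a wrong label of control RNA library 3 were set before their results were seen; all others were set after. The first pattern is the excess of transcripts listed at 0 in CSR. A higher floor or a lower depth in CSR stays possible for the low transcripts. The percent of CSR values at 0 fell at every step of control mean from 32.7% at 1 to 2 FPKM to 3.37% at 4 to 8 FPKM. Under 1 FPKM, where the selection of transcripts bears on it, it was 48.1 and 50.7%. Control values at 0 fell with level too, from 3.27% at 1 to 2 FPKM to 0.612% at 4 to 8 FPKM of the mean over all 6 libraries. A fall with level therefore cannot single out a floor or a lower depth. Neither accounts for the 2 transcripts at 8 FPKM or more in every control library and at 0 in all CSR libraries. Most CSR values were above 0 already at a control mean of 1 to 2 FPKM. Other rows of the same genes had a median log2 fold change of -0.215, from 2 rows, too few to decide. The count of 202 exceeded the highest of the other splits, 35, but an effect of sleep restriction cannot be told apart from a separate processing of the groups, because either would follow the labels.

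The second pattern is the weight of control RNA library 3, without which the count rose from 25 to 259. A swap with a CSR library is argued against, since the splits that put control library 3 among the CSR libraries called at most 1 transcript. For a wrong label, its median place at the 259 transcripts between the control mean (0) and the CSR mean (1) was 0.847. This met the mark of 0.75 set for a wrong label before the value was seen. The 259 transcripts were chosen without control library 3, which by itself can move its place towards CSR. No other library was placed this way, so how far the choice accounts for 0.847 is not known. Only after the value of 0.847 was seen were the zeros brought in. The 423 values at 0 of control library 3 are near the 275 and 330 of the other controls and far from the 1000 to 1415 of CSR. The zeros may come from a separate processing of the groups, so they cannot decide the label. Summed FPKM, also brought in only afterwards, was 145923 in control library 3 and 146497 to 150040 in CSR. In control libraries 1 and 2 it was 130081 and 135270. The mean correlation of control library 3 was 0.916 with the CSR libraries and 0.908 with the other controls. Because the choice of the 259 transcripts may account for 0.847, a wrong label is treated as open rather than as met. It also stays open whether control libraries 1 and 2 came from one animal, which could give the same place; their correlation, 0.932, was the highest of the pairs and the next was 0.921.

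The third pattern is the called CpG of chromosome 6. A methylation difference of the surrounding region is argued against, since the median difference of its neighbours was 1.23 points. A sequence variant at the CpG may give such values, with 11 of the 12 libraries within 15 points of 0, 50 or 100%, but control library 5 stood outside that range at 26.5% of 34 reads, so this stays open; CpGs nearby with a like order of the control libraries are given among the other observations. An effect of sleep restriction on this single CpG was not tested apart from the labels.

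For the RNA comparison 10 splits of the 6 libraries exist, too few for a share under 0.05; 1 split, the real one, gave as many as 25 transcripts, and the highest other gave 3. For gene lists, 5 of the 10 splits gave at least the real count of 1, and the highest other gave 2. In 100 splits of the 12 methylation libraries, 43 called at least 1 CpG and the highest other called 26, so chance cannot be excluded for the called CpG. The 43 pools unlike splits. Most of those that kept CSR libraries 2 and 3 on one side, as the real one does, called at least 1 CpG, and up to 26. Most of those that separated them called none, and the rest at most 2. A count of 1 is therefore common among splits like the real one. For tiles the real count was 0, which all 100 splits reach in any case, so this count tests nothing; the highest other was 1.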

How the results depend on the processing

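Alternatives concerning zeros, on/off values, CSR libraries 2 and 3 as 1 library, control libraries 3 and 5, genotype-like CpGs, level and density classes, and control RNA libraries 1 and 2 as 1 for the lists were chosen after seeing the data. The 25 transcripts became 11 with a pseudocount of 0.1, 10 with a mean of at least 5 FPKM, 7 with control libraries 1 and 2 as 1 library, 77 without the trend and 38 with array weights. They became 16 over transcripts above 0 in all libraries and 92 over transcripts without on/off values within a group; that last filter selects on the spread within groups and so lowers the variance estimate. Rises were 52% of calls, 64.7% with quantile normalization, and 22.1 to 75% over the alternatives that called any. Leaving out single RNA libraries gave 4 to 259. With the replicate block 0 were called (715 at an unadjusted p under 0.05 by limma). Deviations of same-numbered RNA libraries correlated at 0.032, 0.009 and 0.042, so no pairing by number was seen. With 3 libraries per group this cannot exclude one. CSR library 1 correlated more with control library 3 (0.921) than with control library 1 (0.891). Control library 3 also correlated more than the other controls with CSR libraries 2 (0.916) and 3 (0.911), so this does not test pairing. Of the values of named transcripts, 224 kept direction and side of the threshold, 121 no longer passed, 2 newly passed and none reversed.

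The single list became 0 with a pseudocount of 0.1, quantile normalization, the replicate block, control libraries 1 and 2 as 1, an estimated correlation, fry, transcripts above 0 and no on/off values, and 2 with no filter. Leaving out single libraries gave 0 to 2, with 2 without CSR library 2 or control library 3 and 0 without any other.

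The global difference of 0.056 points ranged from -0.095 to 0.159 over left-out libraries (-0.077 without CSR library 4, -0.03 without control library 3, -0.095 without control library 5) was -0.241 without control libraries 3 and 5, and moved most with CpGs weighted by reads, to 1.64 (exact permutation p = 0.335). Classes passing ranged from 0 to 1, and with the replicate block the smallest adjusted p of a class was 0.516.

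The single CpG became 0 with a coverage minimum of 5, no moderation, limma, the replicate block and CSR libraries 2 and 3 as 1, became 2 with no upper coverage limit and 2 with coverage in at least 4 of 6, and 8 without control libraries 3 and 5. Left-out libraries gave 0 to 16: 16 without control 2, 6 without control 1, 4 without control 3 or CSR 1, 3 without CSR 6, 2 without CSR 4, and 0 without CSR 2, 3 or 5 or control 5 or 6. Tiles became 3 with the replicate block, although same-numbered methylation libraries correlated at only -0.009 to 0.018. Of these, 1 on chromosome 9 from 46206001 rests on control library 6 (49.4%, all others 0.8% or less), and 1 from 119321001 mostly on control library 4 (25%, control library 1 at 7.2%, all others 0.6% or less), both with dispersions near 0. The last, on chromosome 20 from 20775001, held 97.3 ± 1.38% in CSR (n = 6) and 56.3% (control 4) to 97.2% (control 2) in control. Its adjusted p was 0.0305 by the moderated model. Tiles became 0 to 3 over left-out libraries (3 without control 2), and stayed at 0 otherwise. For all of these the cause was not tested. Annotation classes, promoters, promoter methylation of the lists and its relation to expression were not run. Simulated CpG differences of 20 points, placed only at CpGs with a level of 30 to 70%, were called in 0% of cases. Depth was not varied, so its part in this is not known.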

Other observations

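The tests in this part were chosen after the values were seen. *Prm1* and *Prm2*, the protamines that pack sperm DNA, were chosen after their values were seen: *Prm1* read 3029, 2572 and 968 FPKM in CSR and 0.093, 0.098 and 877 in control libraries 1 to 3, and *Prm2* read 360, 316 and 145 FPKM in CSR and 0.75, 0.407 and 328 in control. Neither passed the test (adjusted p 0.363 and 0.378 by limma), and *Tnp2* read 2668, 3186 and 3816 FPKM in the same control libraries. Of the tested transcripts 1148 varied by 10 times or more within a group, with values under 0.1 FPKM set to 0.1.

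The CpG with the second smallest p lies on the same chromosome as the called one, from 2893584 to 2893585, and was looked at after the values were seen. It did not pass (adjusted p = 0.199 by the moderated model). It held 96.2 ± 4.13% in CSR and 40.1 ± 25.9% in control (SD, n = 6 each), and control libraries 1 to 6 read 38.5, 52.8, 78.8, 0, 30.3 and 40%. Between them, the CpG from 2839969 to 2839970 (adjusted p = 0.408) held 97.2 ± 3.39% in CSR and 49.5 ± 33.2% in control, with control libraries 1 to 6 at 46.5, 53.1, 100, 0, 33 and 64.4%. At these 3 CpGs control library 3 had the highest and control library 4 the lowest control value. On chromosome 20, CpGs at 20753798, 21286929 and 21409582 that were genotype-like read 96.5, 98 and 98.3% in control library 2 and 0% in control library 4, with CSR means of 99.6, 95.2 and 98.1%; none passed. These CpGs were picked by their small p, so their difference between the groups is no separate evidence, and whether they share a sequence variant or haplotype was not tested. The chromosome 20 tile from 20775001, called with the replicate block, lies between the CpGs at 20753798 and 21286929. It held 76.4 ± 12.9% in control (n = 6), with control libraries 1 to 6 at 76.6, 97.2, 76.6, 56.3, 74.6 and 77%. Control library 2 was again the highest and control library 4 the lowest. Whether the tile shares a variant with these CpGs was not tested.

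CSR methylation libraries 2 and 3 may come from one animal, since they held the same level at 97.8% of the genotype-like CpGs and no other pair at more than 51.2%; a mix-up between samples or close kin would also bear on this and was not tested. If they do, p-values that count 6 CSR libraries are too small. Counted as 1 library, they gave a global difference of 0.02 points (exact permutation p = 0.935).

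The mean methylation of CpGs with a level under 10% varied between libraries, with 3.31% in CSR library 4 and 2.94% in control library 6. Incomplete bisulfite conversion is a candidate explanation. Mitochondrial CpGs, used here as a measure of unconverted reads, had 1.66% methylated reads in CSR library 4 and 1.23% in control library 6, and 0.421 to 0.979% in the others. Over the 12 libraries the low-level class correlated with them at Pearson r = 0.98 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 4e-05) and Spearman rho = 0.965 (permutation p = 1e-05). Without CSR library 4 and control library 6, r was 0.959 (permutation p = 4e-05). It was 0.996 within CSR and 0.955 within control (n = 6 each, exact permutation p = 0.00139 and 0.00417). These 4 relations were computed as one family.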
